A study of Mus musculus with 2 samples.

How the data were processed

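ATAC-seq was measured in the heart of B6NCrl mouse embryos at 15.5 days, in 2 biological replicates that form 1 group: replicate 1 from 78 embryos and replicate 2 from 62, pooled male and female. Per the labels the DNA was fragmented by Nextera tagmentation with a size range of 200 to 750, and positions are on mm10. The aligner and the peak caller are not given in the sources used here.

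The deposited files used here are peak lists in which a row is a summit. Per the file headers of the library descriptions, each replicate has pseudoreplicated peaks, which recur in parts of that library's own reads, and peaks that pass a threshold of the irreproducible discovery rate (IDR). The whole series has replicated peaks, from both libraries' reads together (51.4% of their intervals are in both replicates' own lists), pseudoreplicated and IDR-thresholded peaks of the pooled reads, and conservative peaks that pass the IDR threshold between the true replicates. The deposited enrichment of each peak is a ratio, the fold over the local background that the authors' peak caller computed, and is used only to describe and rank peaks within a list. The deposited −log10 p of each peak was also made by the authors' peak caller, with no normalization between lists. The IDR score of the ranked list, at most 1000, was deposited by the authors per peak over both replicates, and the conservative list starts at a score of 540. The ranked list also holds the −log10 p of each of its 2 inputs, which as deposited carry no sample name, and these were compared as first and second input without assigning them to a replicate.

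Read depth is unknown, because the lists hold no counts. The spread of a value is given as the SD over the 2 replicates' own lists or over the genes of a list. An SD over the replicates' lists belongs to their mean, and is not the precision of the replicated-list value beside it. Absence of a peak means only that none was listed at this depth. Intervals that share start and end were merged into 1, which keeps the highest enrichment and the summit with the highest −log10 p, and intervals outside the 21 main chromosomes were left out of the comparisons. In the replicated list 87750 summits gave 53616 intervals, of which 41.4% held several summits. Values computed from a replicate's own list are called without the other replicate.

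An interval counted as shared when the overlap was at least 50% of either interval, against 20 shuffles of the intervals within their chromosomes. The rescue ratio is the larger over the smaller of the conservative and the pooled IDR-thresholded list sizes in summits, and the self-consistency ratio that of the 2 replicates' IDR-thresholded lists. Annotation used the GENCODE mouse release 21 reference with 21829 protein-coding genes and the start sites of all their protein-coding transcripts. By its midpoint each interval was placed in a promoter (within 1 kb of a start site), exon, intron or intergenic sequence, in that order, and compared with 100 shuffles. For the gene comparisons and motifs an interval that came within 1 kb of a start site counted as a promoter peak (16165 intervals) and any other as distal (37451).

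There were 23 gene lists: 6 of heart muscle with 107 distinct genes, 4 of other cell types of the heart, 2 of blood, 7 of other organs, 2 of Hox genes and 2 controls. Some genes belong to more than 1 list, such as Myl2, Nppa and Pitx2, and 2 list names matched no gene of the annotation. Most ventricular and most atrial genes also belong to another list of heart muscle, so the results of these lists are not separate. The share of a list's genes with a promoter peak was compared with all other protein-coding genes by two-sided Fisher's exact tests. The mean number of distal peaks within 50 kb of a gene's start sites was compared by two-sided permutation tests with 100000 random lists of the same size, matched on 5 classes of gene length and 3 of gene density. In 6 contrasts the difference between a pair of lists was tested by 100000 relabellings of their genes, with shared genes left out. Genes, not samples, are the unit of these tests, so they compare genes within this tissue, and neighbouring genes share peaks. All p-values of a family were adjusted by Benjamini and Hochberg's method, with a threshold of 0.05.

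For 26 motifs the consensus on either strand within 50 bp of the summit was compared with a flank by exact McNemar tests. Distal and promoter peaks were tested separately. The flank lay 250 to 350 bp from the same summit whatever the width of the interval (median 442 bp), so it often fell outside the interval. Ratios of shares have 0.5 added to each count. Distal peaks within 12.5 kb of each other were joined into domains, the 100 with the most peaks were given their nearest protein-coding start site, and overlap with the heart lists was tested by Fisher's exact test. For the balance of the 2 inputs, the median log2 ratio of their −log10 p over the ranked peaks within 50 kb of a list's start sites, centred on all peaks, was placed among 10000 random peak sets matched in 10 classes of strength. Sequence was compared with the mitochondrial genome by blastn 2.17.0, and all else was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

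The groups, gene lists, motif sequences, tests and alternatives were fixed before the data were examined, except that leaving out list members within 100 kb of an earlier member was added later. The test of a lower share of cardiomyocytes was also written later, after the balance had been seen. The named genes were fixed as 12 core genes, the 3 members of each list with the most distal peaks and its members with none where these were 5 or fewer, the 15 genes with the most distal peaks, the 10 strongest distal and 5 strongest promoter peaks, the 10 largest domains and the 5 strongest unshared intervals of each replicate. Members of a list with or without a promoter peak, the heart genes nearest to large domains and pairs of neighbouring genes were named in addition, after their values were seen.

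The tests were tested on simulated data. For the simulated lists, contrasts and promoters a call was an unadjusted p of at most 0.05. Adjusted calls are stricter and many real lists are smaller, so these rates may overstate the power of the real tests. Random lists of 25 genes were called in 3.5% of 200 runs with no planted difference, and in 31%, 72.5% and 96.5% with planted ratios of 1.5, 2 and 3. The contrasts called 5% of 100 runs with no difference and 13%, 26% and 70% at those ratios. The promoter test called 5% of 200 runs at the genome-wide share, 92% at a share of 90% and 86.5% at 30%. Of 30 motifs planted in 10 runs of 20000 peaks (MEF2, AP-1 and NFY) 30 were called, with 2 calls among 230 that were not planted. A first set with CTCF in place of AP-1 also gave 30 of 30, with 3 calls among 230. These 3 calls were all of the NEUROD E-box, which the CTCF consensus can contain. In the motif runs summits and flanks were random sequence of the same base content. Motifs were planted at a higher share than most real ones had. Real distal summits had 55.0% G and C against 47.6% in flanks, so the motif rates may not carry over to the real tests.

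Alternatives were the conservative and the pooled pseudoreplicated list, each replicate alone, 1 start site per gene, promoters of 500 and 2500 bp, windows of 20 and 100 kb, random genes without matching, a background without olfactory and vomeronasal receptor genes, and presence of a distal peak in place of its number. For motifs they were 100 bp on each side of the summit, a flank centred 1 kb away and the reversed consensus at the same summits, for domains joining distances of 5 and 25 kb, and for shared intervals other overlap rules and thresholds. The −log10 q of the peaks and the signal tracks were not used here.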

Results

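ATAC-seq, which marks open chromatin by where a transposase inserts sequencing adapters, was performed on the heart of B6NCrl mouse embryos at 15.5 days, a stage at which the chambers are septated and the ventricular wall is thickening. The series holds 1 group of 2 biological replicates, made from the pooled hearts of 78 embryos of both sexes (replicate 1) and of 62 (replicate 2). It holds no other tissue, stage or treatment, so the comparisons possible are those between the replicates, between groups of genes within the tissue, and between peak summits and their own flanks. Per the labels the purpose of the series is a map of accessible chromatin in this tissue. The deposited lists give peaks and their values and no read counts, so the depth of each library is unknown and no interval based on counts is given. Errors are the SD over the 2 replicates' own peak lists, or the SD over genes where so stated, and coordinates are mm10. An SD over the replicates' lists belongs to their mean, which can differ from the replicated-list value. Dab2ip had 22 distal peaks in the replicated list, against 12 ± 0 in the replicates.

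Accessible chromatin of the embryonic heart formed 53616 distinct intervals in the replicated list, which per the labels holds replicated peaks of both libraries' reads together. Of these, 51.4% were found in both replicates' own lists. The intervals covered 29.3 Mb, or 1.07% of the genome, with a median width of 442 bp and a median enrichment of 4.39-fold over local background. Replicate 1 alone gave 42265 intervals and replicate 2 gave 39469. Of these, 28277 (66.9%) of replicate 1 were found in replicate 2 and 28230 (71.5%) of replicate 2 in replicate 1, against 1.12% ± 0.0425 and 1.21% ± 0.0456 (SD, 20 shuffles) when the other set was placed at random. Shared intervals were the stronger ones: their median enrichment was 6.06-fold in replicate 1 and 6.63-fold in replicate 2, against 3.56-fold and 3.90-fold for intervals not shared. The rescue ratio, which compares the lists of reproducible peaks from true and from pooled pseudoreplicates, was 1.01, and the self-consistency ratio between the replicates was 1.05. Across 89513 ranked peaks the values of the 2 inputs to the reproducibility ranking had a Pearson r of 0.784 and a Spearman rho of 0.691. These correlations are across peaks, which are not independent replicates, and carry no p.

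Promoters of protein-coding genes held 29.3% of the replicated intervals, 11.1 times the 2.64% ± 0.0728 (SD, 100 shuffles) of randomly placed ones, and the share was above every one of the 100 shuffles. Introns held 34.9%, exons 3.33% and sequence between genes 32.4%, the last against 57.8% in shuffles. In the replicates' own lists the promoter share was 36.1% ± 2.36 (SD, n = 2), and in the conservative list of 20181 reproducible intervals it was 56.2%. Chromosome 11 was the densest, with 32.1 intervals per Mb (24.8 ± 1.11 in the replicates, SD, n = 2), followed by chromosomes 19 and 17 at 25.6 and 25.3. The sex chromosomes were the sparsest: X had 5.72 intervals per Mb and Y had 0.207, from 19 intervals, in these pools of both sexes.

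Promoters of cardiac genes were open almost without exception. All 26 cardiac transcription factors had a peak within 1 kb of a transcription start site (adjusted p = 7.43e-05 by Fisher's exact test), as did all 17 genes of cardiac metabolism and hormones (0.00167) and all 12 ventricular genes (0.00955), against 64.0% of other protein-coding genes. Of the 28 sarcomere genes 26 had one (92.9%, adjusted exact p = 0.00167), the exceptions being Obscn, which encodes a giant scaffold protein of the sarcomere, and Xirp2. Of the 26 genes of calcium handling and conduction 24 had one (92.3%, adjusted exact p = 0.00294), without the pacemaker channel gene Hcn2 and Sln, which encodes the calcium pump inhibitor sarcolipin. The other cell types of the heart were also covered: 25 of 26 endothelial and endocardial genes (96.2%, adjusted exact p = 0.000921, all but the von Willebrand factor gene Vwf) and 20 of 22 epicardial and fibroblast genes (90.9%, 0.0105, without Dpt and Msln) had a promoter peak. All 20 housekeeping genes had one (adjusted exact p = 0.000921), and each of these 8 lists lay above other genes in both replicates. The ventricular list shares most of its genes with the other lists of heart muscle. The atrial list (11 of 13, without Bmp10 and Sln, adjusted exact p = 0.169), smooth muscle and pericytes (11 of 12, without Mylk, 0.0810), neural crest and cardiac nerve (8 of 13, 1), the erythroid list (7 of 16, 0.134) and the brain list (20 of 31, 1) did not pass the test. Without replicate 2 neural crest (23.1%, adjusted exact p = 0.0134) and erythroid genes (31.2%, 0.0261) passed below other genes, and without replicate 1 smooth muscle and pericyte genes passed above them (91.7%, 0.0492). In the conservative list the calls of the calcium list (69.2%, adjusted exact p = 0.134), the endothelial list (50%, 0.883) and the epicardial list (54.5%, 1) ended. The endothelial share there fell below that of other genes. The epicardial call also ended without replicate 1 (77.3%, 0.205), and the endothelial call with 1 start site per gene (76.9%, 0.130).

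Promoters of other organs' genes mostly lacked a peak. Of 18 immune genes only the one for the adaptor protein Tyrobp had a promoter peak (5.56%, adjusted p = 3.85e-06 by Fisher's exact test). Of 24 liver genes 4 had one (16.7%, adjusted exact p = 2.00e-05), namely Apob, Foxa3, Trf and Vtn, so that albumin and alpha-fetoprotein were among the 20 without. Germ cell and pluripotency genes (3 of 16, 0.000921) had one at Dazl, Pou5f1 and Zp3, kidney genes (3 of 14, 0.00276) at Lrp2, Six2 and Slc12a3, and genes of gut, pancreas and lung (5 of 19, 0.00237) at Cdx1, Foxa1, Foxa2, Nkx6-1 and Pdx1. Epidermal genes (4 of 14, 0.0128) had one at Evpl, Krt10, Perp and Tfap2c. Skeletal muscle genes were open in 7 of 24 (29.2%, adjusted exact p = 0.00200), among them Acta1 and Tnni2. Among Hox genes, which pattern the body axis, 5 of 16 posterior (Hoxa10, Hoxa11, Hoxc10, Hoxc13 and Hoxd13; 0.0124) and 5 of 15 anterior members (Hoxa1, Hoxa4, Hoxb4, Hoxd1 and Hoxd3; 0.0346) had a promoter peak. Olfactory receptor genes, a control list, had one in 11 of 1133 (0.971%). These members were named after their values were seen, and each of the 10 lists lay below other genes in both replicates. Without replicate 1 the liver share was 8.33%, the kidney share 14.3%, the germ cell share 6.25%, the immune share 0% and the olfactory share 0.353%. Without replicate 2 the share of gut, pancreas and lung was 15.8% and that of immune genes 0%, and without replicate 1 the anterior Hox call ended (40%, 0.142), as did the epidermal call with promoters of 2500 bp on each side (42.9%, 0.0992).

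Distal peaks, more than 1 kb from any start site, gathered around genes of the working myocardium. Sarcomere genes had 7.61 ± 4.01 distal peaks within 50 kb (SD over 28 genes), 3.05 times as many as random genes matched for length and gene density, and cardiac transcription factors had 5.88 ± 3.85 (SD over 26 genes), 2.55 times as many. Both had an adjusted permutation p of 0.000153, from the smallest raw p that 100000 random lists can give. Ventricular genes had 4.75 ± 3.55 (2.47 times, adjusted permutation p = 0.00445), genes of calcium handling and conduction 5.69 ± 4.40 (2.13 times, 0.000690), and endothelial and endocardial genes 5.04 ± 3.24 (2.01 times, 0.00230). In the replicates' own lists the ratio was 3.12 ± 0.0527 for sarcomere genes, 2.86 ± 0.334 for cardiac transcription factors, 2.66 ± 0.0506 for ventricular, 2.07 ± 0.0664 for calcium and 2.35 ± 0.546 for endothelial genes (SD, n = 2), above 1 in both. Atrial genes (2.23 times, adjusted permutation p = 0.0158), smooth muscle and pericyte genes (2.10 times, 0.0207) and housekeeping genes (1.73 times, 0.0240) also had more, above 1 in both replicates. The ventricular and atrial calls are not separate from the others, since most of their genes are also in another list of heart muscle. Olfactory receptor genes had 0.242 ± 0.713 (SD over 1133 genes), 0.116 times the random mean and the only list that passed as lower (0.000153, below 1 in both replicates). The atrial call ended without replicate 1 (1.83 times, adjusted permutation p = 0.164), the smooth muscle call without replicate 2 (1.92 times, 0.0637). The housekeeping call ended with a window of 20 kb (1.41 times, 0.419).

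The remaining 14 lists did not pass this test. Genes of cardiac metabolism and hormones had 1.59 times the random mean (adjusted permutation p = 0.127), although in each replicate's own list the ratio was 1.96 with an adjusted permutation p of 0.0204 and 0.0245. Neural crest and cardiac nerve stood at 1.59 (adjusted permutation p = 0.189), gut, pancreas and lung at 1.29 (0.543), anterior Hox at 1.29 (0.543), skeletal muscle at 1.28 (0.517) and epicardial and fibroblast genes at 1.19 (0.649). Germ cell genes stood at 1.19 (0.680), immune genes at 1.13 (0.774), erythroid genes at 1.01 (0.989), kidney genes at 1.00 (0.989) and liver genes at 0.998 (0.989). Posterior Hox genes stood at 0.923 (0.989), brain genes at 0.784 (0.575) and epidermal genes at 0.761 (0.676). Without replicate 2 posterior Hox genes stood at 0.514 and erythroid genes at 0.605.

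**Figure D1:**
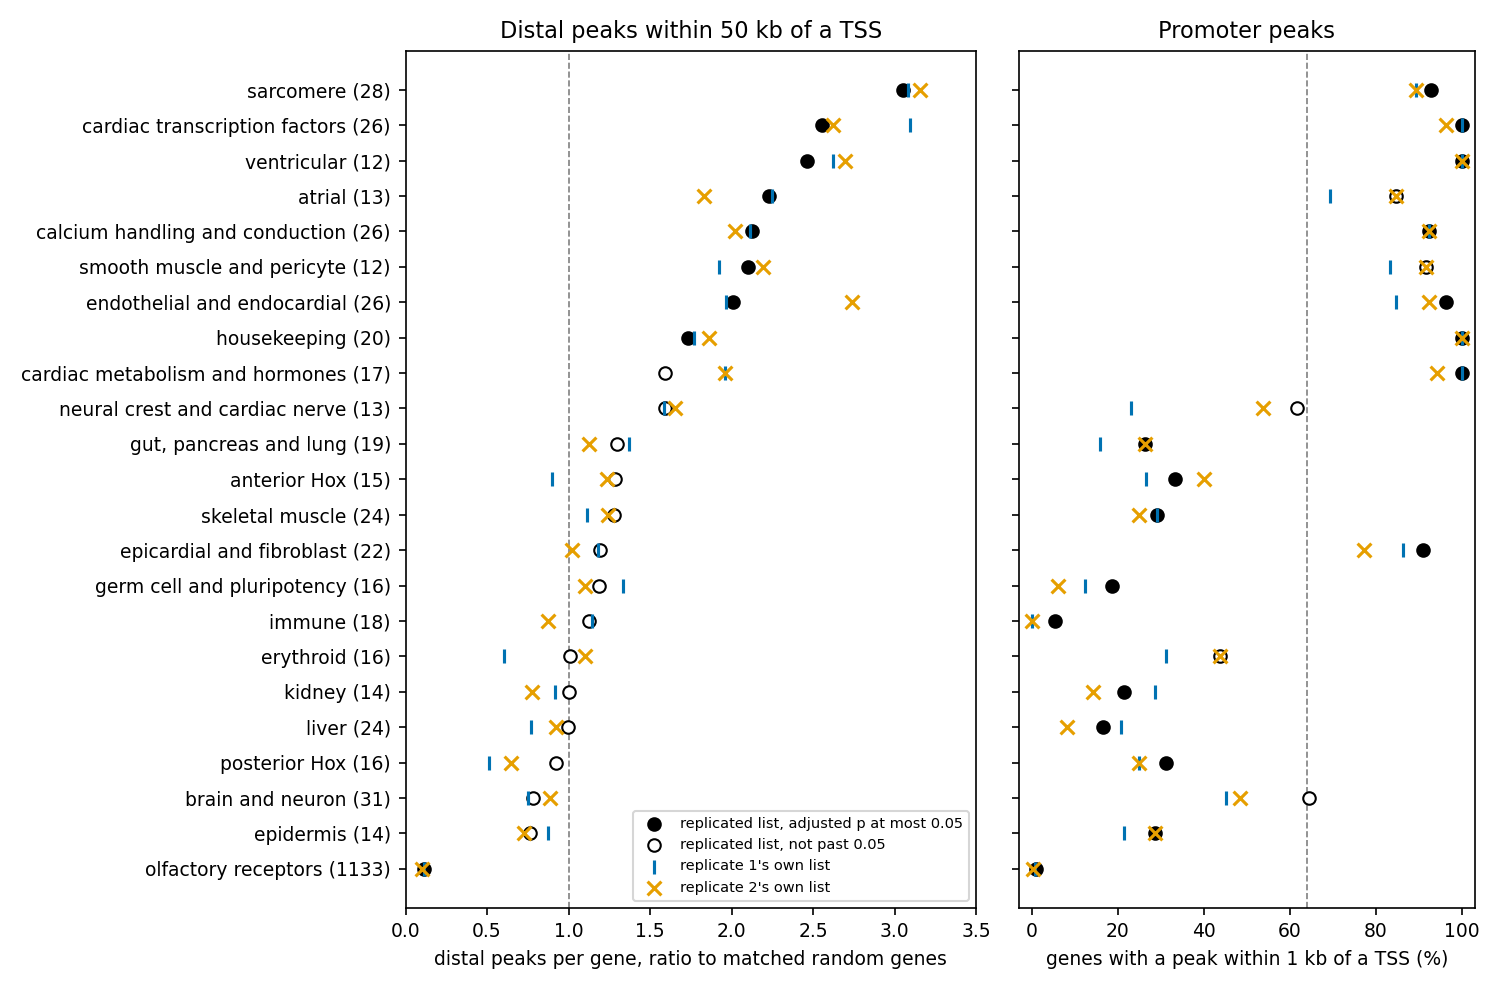
Left, mean number of distal peaks within 50 kb of a start site per gene, as a ratio to matched random genes (dashed line at 1); right, percentage of genes with a peak within 1 kb of a start site (dashed line, all protein-coding genes, 64.0%). Each row is a gene list with its number of genes, circles are the replicated list (filled where the adjusted p is at most 0.05), and bars and crosses are the own lists of replicates 1 and 2; sarcomere genes reach 3.05 in the left panel and olfactory receptors 0.116.

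Among the sarcomere genes, Actn2, which encodes the alpha-actinin of the Z-disc, had 16 distal peaks (11.5 ± 2.12 in the replicates, SD, n = 2), Tnni1 for slow skeletal troponin I, which is the form of the fetal heart, 13 (9 ± 2.83), and Myl2 for the ventricular regulatory light chain 13 (9.5 ± 0.707). Around calcium handling genes the L-type channel gene Cacna1c had 18 (11 ± 1.41) and the potassium channel gene Kcnh2 16 (9.5 ± 0.707), while Kcnd2 had none. Mef2d led the transcription factors with 13 (11 ± 1.41) and Pitx2, a left-right asymmetry gene, had none. The myoglobin gene Mb had 12 (12 ± 1.41), the atrial light chain gene Myl4 11 (4.5 ± 2.12), and Irx4, a transcription factor of ventricular identity, 8 (6 ± 2.83). In the endothelial list Notch1 had 13 (9.5 ± 0.707) and Egfl7 12 (12 ± 4.24). Xirp2, Cox6a2 and Lmo2 had none. In the mural lists Notch3 (9 ± 4.24) and Cspg4 (5 ± 1.41) had 10 each, and Acta2, Tagln and Rgs5 had none. Scx, a tendon and valve transcription factor, led the epicardial and fibroblast list with 7 (5.50 ± 0.707), and Twist1 had none. Mpz led the neural crest list with 10 (5.5 ± 0.707), and Gfra3, Phox2b and Plp1 had none. The housekeeping genes Ubc and Actb had 11 (8 ± 0) and 9 (7.5 ± 0.707), and B2m had none. Of the genes with none, Pitx2, Cox6a2, Twist1, Acta2 and Gfra3 had 1 in a single replicate's own list. The conservative list held fewer at each gene named here with a distal peak, such as 8 at Mef2d, 6 at Actn2 and 3 each at Cacna1c and Kcnh2.

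Among the core cardiac regulators the number of distal peaks ranged from 3 at Tbx20 to 12 at Nkx2-5 and Gata4. Nkx2-5 on chromosome 17 had 12 (9 ± 2.83 in the replicates, SD, n = 2), and the strongest lay 47.7 kb from its start site at 26892450 to 26893048 with 10.8-fold enrichment. Gata4 on chromosome 14 had 12 (10.0 ± 2.83), the strongest at 63164332 to 63165184 inside an intron of Fdft1, 48.9 kb away (9.76-fold). Hand2 on chromosome 8 had 11 (8.50 ± 0.707), the strongest 32.9 kb away between genes at 57353453 to 57354269 (10.3-fold). Tbx5 had 6 and Mef2c 5 (4.5 ± 0.707 each), with the strongest in introns of the genes themselves, at 119844999 to 119845383 on chromosome 5 (6.81-fold) and at 83532028 to 83532467 on chromosome 13 (11.1-fold). Tbx20 had 3 (2.00 ± 0), none above 3.73-fold. In the conservative list Nkx2-5 and Hand2 had 5 each, Mef2c 4, Gata4 3, Tbx5 2 and Tbx20 0.

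The neighbouring genes for the alpha and beta cardiac myosin heavy chains, Myh6 and Myh7, had 11 (9 ± 1.41) and 8 (6.50 ± 0.707) distal peaks, which they partly shared. The strongest, at 55003765 to 55004975 on chromosome 14 (8.07-fold), lay 9.74 kb from the Myh7 start site and 37.4 kb from that of Myh6. Ryr2, the calcium release channel gene, had 8 (5 ± 1.41), the strongest at 12133467 to 12134314 on chromosome 13 (10.8-fold), and Tnnt2 had 7 (5 ± 2.83), the strongest inside an intron of Tnni1 (6.0-fold). The natriuretic peptide gene Nppa had 5 (5.50 ± 0.707), the strongest 21.1 kb away (8.17-fold), and the pacemaker channel gene Hcn4 had 6 (3.5 ± 0.707), the strongest in its own intron at 58847574 to 58848228 on chromosome 9 (6.29-fold). All 12 core genes had a promoter peak in the replicated list, and Tbx5 alone lacked one in replicate 2. In the conservative list Tbx5, Nppa and Hcn4 lacked one. There Myh6 had 5 distal peaks, Myh7 and Nppa 4 each, Tnnt2 and Hcn4 2 each, and Ryr2 1.

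**Figure D2:**
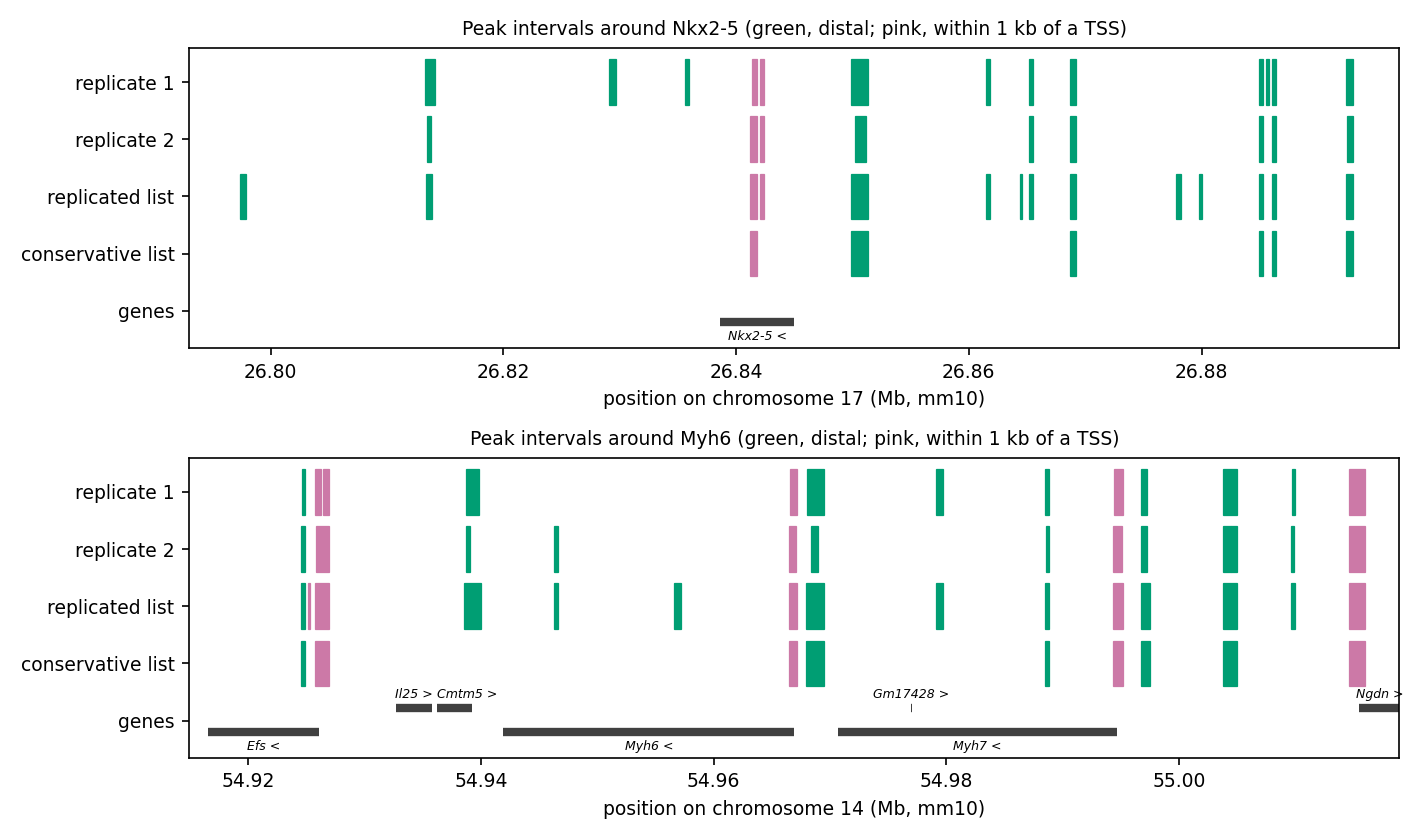
Peak intervals within about 50 kb of Nkx2-5 (top) and Myh6 (bottom), in each replicate's own list, the replicated list and the conservative list, along chromosomes 17 and 14 in Mb; green intervals are distal, pink ones lie within 1 kb of a start site, and arrowheads give the strand of each gene. The 12 distal intervals of the replicated list around Nkx2-5 lie mostly on its upstream side, and the strongest distal interval of the Myh6 region, at 55003765 to 55004975, is matched by an interval in all 4 lists.

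Direct contrasts between lists asked whether heart genes have more distal peaks than genes of a related or unrelated tissue. Sarcomere genes exceeded skeletal muscle genes by 4.73 peaks per gene (7.61 against 2.88; adjusted permutation p = 0.000120), and cardiac transcription factors exceeded brain genes by 4.30 (5.88 against 1.58; 6.00e-05, the smallest the relabellings can give). Endothelial genes exceeded erythroid genes by 2.85 (5.04 against 2.19; adjusted permutation p = 0.00506), and calcium handling genes exceeded kidney genes by 3.19 (5.69 against 2.5; 0.0280). All 4 differences were positive in both replicates. Atrial and ventricular genes differed by -0.212 (adjusted permutation p = 0.904), and epicardial and liver genes by 0.477 (0.609). Without replicate 1 the contrast of mean distal peaks: atrial minus ventricular was -0.955 and the contrast of mean distal peaks: epicardial and fibroblast minus liver was 0.129, and without replicate 2 the former was -0.359. Without replicate 1 the difference between cardiac transcription factors and brain genes was 2.73, and with a window of 100 kb that between endothelial and erythroid genes no longer passed (2.08, adjusted permutation p = 0.298).

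Of the 9 motifs of the heart group, 6 were more frequent at distal summits than in flanks (MEF2, GATA, TEAD, MEIS, SRF and HAND), NKX2 was less frequent, and TBX and ERR did not pass. The MEF2 consensus, bound by the MEF2 family of muscle transcription factors, was present within 50 bp of 1.44% of 37451 distal summits, 6.24 times as often as in flanks of the same peaks (6.66 ± 1.54 in the replicates, SD, n = 2). A MYOD-type E-box, bound by basic helix-loop-helix factors, was found at 6.64% (2.39 times; 2.48 ± 0.0219), TEAD, bound by the effectors of Hippo signalling, at 8.69% (1.46 times; 1.51 ± 0.00706), and GATA at 6.65% (1.31 times; 1.31 ± 0.0544). MEIS (1.63 times), the SRF CArG box (1.39 times) and AP-1 (2.37 times; 2.30 ± 0.140) were also more frequent, in both replicates. The architectural factor CTCF had the largest ratio, 21.9, at 2.07% of distal summits, although without replicate 2 it was 10.5. The adjusted p by exact McNemar tests was 6.19e-81 for MEF2, 4.88e-139 for the MYOD E-box, 2.53e-46 for TEAD, 2.44e-19 for GATA and 0.00160 for SRF. RFX (3.84), SP and KLF (2.48), PU.1 (2.13), NFY (1.61) and the USF E-box (4.90) passed too, PU.1 not in the conservative list (1.59, adjusted exact p = 0.112), as did NRF1 (7 times, from 17 and 2 summits; without replicate 2 it was 2.45, adjusted exact p = 0.132). The HAND and TWIST E-box (1.07) and the NEUROD E-box (1.18) also passed, and did not without replicate 2 (1.06 each, 0.0927 and 0.392). In the conservative list both ratios fell below 1 (0.897 and 0.951, adjusted exact p = 0.0571 and 0.743). Every match of the NEUROD consensus also holds the HAND and TWIST consensus on the other strand, so these 2 results are not separate.

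The NKX2 consensus, by contrast, was at 0.836% of distal summits, 0.732 times its share of flanks (0.789 ± 0.0492 in the replicates, SD, n = 2; adjusted p = 5.05e-05 by exact McNemar test), and FOX (0.848) and RUNX (0.646) were also less frequent. Summits had more G and C than flanks, 55.0% against 47.6%. Against the reversed consensus at the same summits, which has the same bases, NKX2 (1.77), FOX (1.16) and RUNX (2.42) had ratios above 1. USF stood at 0.946, MEF2 at 51.4, TEAD at 2.86, MEIS at 2.30 and GATA at 1.84. These ratios compare different words, whose background frequency can differ. NKX2 was at 1.14% of flanks, above the 0.473% of its reversed consensus at summits, and no flank share of reversed words was computed. The ratios therefore do not show whether a motif is more or less frequent at summits. Without replicate 1 the call of RUNX ended (0.860, adjusted exact p = 0.216), as did that of FOX (1, 1). In the conservative list those of NKX2 (0.703, adjusted exact p = 0.0571) and FOX (0.887, 0.541) ended, and with the flank 1 kb away that of FOX (0.984, 0.873). TBX (1.04), ERR (1.28), ETS (1.51), YY1 (7, from 3 and 0 summits), SOX (0.952), HNF1 (0.6) and HNF4 (1.09) did not pass at distal summits. ETS passed without replicate 1 (2.53), with the flank 1 kb away (4.08) and in the conservative list (4.43), and YY1 stood at 3 and 1.4 without replicates 1 and 2. With 100 bp on each side ERR (1.27, adjusted exact p = 0.0133) and YY1 (10.3, 0.000198) passed, and against the reversed consensus ERR (3.55) and HNF4 (2.57) passed as more frequent and SOX (0.663), TBX (0.523) and ETS (0.361) as less frequent.

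Of the 12 motifs more frequent at promoter summits than in flanks, 10 were also more frequent at distal ones, and ETS and YY1 were not. NFY was at 10.8% of 16165 promoter summits (7.09 times the flanks; 7.35 ± 0.257 in the replicates, SD, n = 2) and SP and KLF at 11.6% (4.80 times; 5 ± 0.666). NRF1 (7.79), ETS (7.19), the USF E-box (6.91), RFX (3.22), PU.1 (2.30), YY1 (2.28) and the MYOD E-box (1.29) were more frequent in both replicates, the last not in the conservative list (1.15, adjusted exact p = 0.0715). With the flank 1 kb away ratios were larger for SP and KLF (14.0), ETS (20.6), NRF1 (23.4), YY1 (29.7), RFX (7.91) and USF (12.6). CTCF had 13 times (7 without replicate 2) and MEF2 2.56 times (4.05 without replicate 1). The SRF CArG box passed narrowly (1.45, adjusted p = 0.0489 by exact McNemar test) and in neither replicate alone (1.44, 0.0642; 1.03, 0.966). GATA was less frequent than in flanks (0.514; 0.461 ± 0.0468; 0.270 with the flank 1 kb away), as were NKX2 (0.278), HAND and TWIST (0.619), TBX (0.352), SOX (0.655), FOX (0.707), RUNX (0.532), the NEUROD E-box (0.727), TEAD (0.852), HNF4 (0.310, not without replicate 1, adjusted exact p = 0.0580) and ERR (0.298; 0.569 and adjusted exact p = 0.117 without replicate 2). Against the reversed consensus TEAD (1.74), NKX2 (1.31), HAND (1.90), FOX (1.90), NEUROD (2.47) and RUNX (2.57) turned to ratios above 1, and GATA stayed below (0.790). These ratios too compare different words and not summits with flanks. SP and KLF had no such control at either kind of summit, since its consensus reads the same reversed. Its bases are all G or C, and promoter summits had 66.1% G and C against 57.4% in their flanks. AP-1 (1.22), MEIS (0.981) and HNF1, with no match, did not pass. Compared directly, GATA (odds ratio 5.21 by Fisher's exact test, adjusted exact p = 1.28e-180) and MEF2 (4.13, 1.25e-33) marked distal over promoter summits, and SP and KLF (0.106) and NFY (0.227, 2.53e-299) the reverse, while RFX (0.823, 0.356) and PU.1 (0.905, 0.441) did not differ past the threshold. Base composition differed too: promoter summits had 66.1% G and C against 55.0% at distal ones, and the reversed GATA consensus was at 3.61% of distal and 1.71% of promoter summits.

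**Figure D3:**
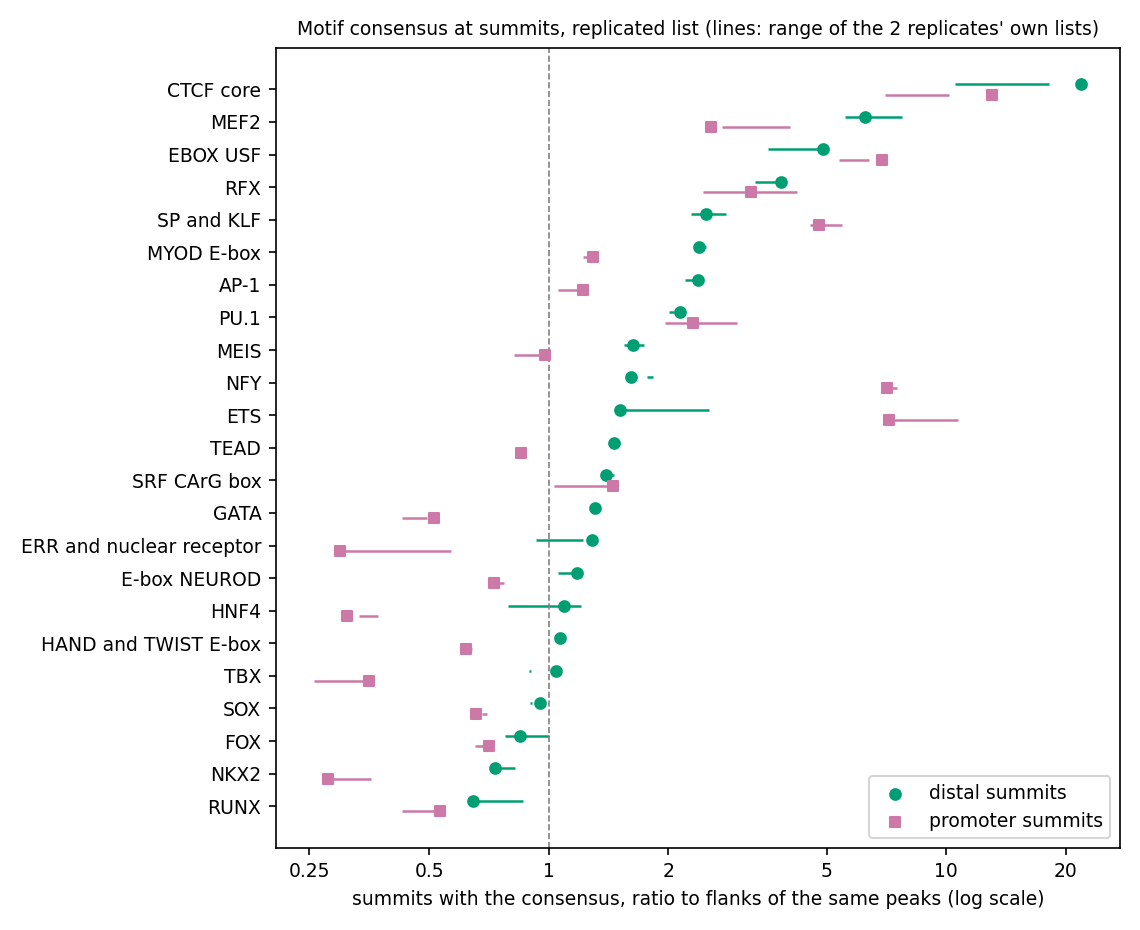
Ratio of the share of summits that hold each consensus to the share of flanks of the same peaks, on a log scale, for distal (circles) and promoter (squares) peaks of the replicated list; lines span the 2 replicates' own lists and the dashed line marks equal shares. CTCF reaches 21.9 and MEF2 6.24 at distal summits, and GATA lies at 1.31 at distal and 0.514 at promoter summits.

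Genome-wide, 13974 of 21829 protein-coding genes (64.0%) had a promoter peak, and 32.2% had no distal peak within 50 kb. Tns1, which encodes the focal adhesion protein tensin 1, and Sorbs1, for a scaffold of cell adhesions, had the most distal peaks, 34 each (26.5 ± 0.707 and 23.0 ± 2.83 in the replicates, SD, n = 2). They were followed by Gse1 (29; 21.5 ± 2.12), the corepressor gene Ncor2 (29; 17.5 ± 0.707), the exchange factor gene Trio (28; 17 ± 1.41), the zinc finger gene Casz1 (25; 18 ± 2.83) and the splicing regulator gene Rbfox2 (24; 17.5 ± 2.12). Rbm20, which controls titin splicing, had 22 (14.5 ± 0.707), as had Mical3 (17.5 ± 2.12), Kalrn (14 ± 4.24), Sh3pxd2a (15 ± 1.41) and Mical2 (18.5 ± 0.707). The basement membrane collagen gene Col4a1 (16 ± 0) and Dab2ip (12 ± 0) also had 22, and Foxp1 had 21 (11.5 ± 0.707). The conservative list held fewer at each of these genes, such as 12 at Tns1 and 9 at Sorbs1.

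Distal peaks lying close together formed 69 domains of 10 or more distal peaks (21 without replicate 1 and 16 without replicate 2). The largest held 19 over 103.5 kb at Tns1 (chromosome 1, 73905523 to 74008993; 17 intervals in replicate 1 and 16 in replicate 2), followed by domains nearest to Sfi1 (18), Lrrc74a (17), Zfp36l2 (17), Il17b (16), Kdm6b (16), Cstad (15), the retinoic acid receptor gene Rara (15), Meox1 (14) and 2900026A02Rik (14). Of the 100 genes nearest to the 100 largest domains, 8 were among the 107 genes of the heart lists (p = 3.28e-08 by Fisher's exact test). This test was not matched for gene length or density, and it draws on the same distal peaks as the list tests. The domains were not examined for multicopy sequence. The 8 genes were Mef2d, Hand2, Irx4, Nkx2-5, Ldb3, Mef2a, Kcnh2 and Mb, named after their values were seen. The odds ratio of heart-list genes nearest to the top 100 domains was 19. Without replicate 1 it was 11.4 and without replicate 2 21.8, and with joining distances of 5 and 25 kb it was 8.84 and 8.75.

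The strongest distal peaks lay outside the heart gene lists. The highest enrichment was 55.8-fold at 69355469 to 69355735 on chromosome 2, 12.99 kb from Abcb11, then 54.9-fold on chromosome X, 35.5 kb from Pak3, 47.1-fold on chromosome 10, 58.9 kb from Gm5426, 45.0-fold on chromosome 5, 1766 kb from the nearest start site, that of G6pd2, and 38.0-fold on chromosome 2, 53.2 kb from Frmd4a. The next 5, with the nearest start sites those of Hic2 (30.7-fold, 11.2 kb), Tyrp1 (30.1-fold, 831 kb), Galc (29.4-fold, 1182 kb), 4930467E23Rik (28.5-fold, 55.2 kb) and Nxph1 (28.4-fold, 940 kb), completed the 10 strongest, of which 8 either aligned to mitochondrial DNA or held a summit sequence present more than once in the genome. The strongest promoter peaks were those of Kifap3 (27.6-fold), Tmem218 (25.9-fold), Cbwd1 (25.1-fold), Selenok (25.1-fold) and Golph3l (25.02-fold).

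Peaks found in only 1 replicate were mainly weak and away from promoters. Replicate 1 had 13988 (33.1%) and replicate 2 had 11239 (28.5%), of which 9.72% and 15.7% lay at promoters, against 47.9% and 47.8% of shared ones. The strongest unshared interval of replicate 1 was at 18181207 to 18181717 on chromosome 1, 35.6 kb from Crisp4 (12.6-fold, rank 2920 in its list), followed by intervals 69.7 kb from Cd28 (11.9-fold), 339 kb from the nearest start site, that of Gramd3 (11.6-fold), in an intron of Slc4a10 (11.1-fold) and in an exon of Macf1 (10.9-fold). In replicate 2 it was the promoter interval of Nol10 at 17348286 to 17348723 on chromosome 12 (11.6-fold, rank 5377), followed by intervals 15.7 kb from A2ml1 (11.6-fold), 264 kb from the nearest start site, that of Stmn2 (10.3-fold), in an intron of Prcp (10.2-fold) and at the sodium channel gene Scn2a (10.1-fold).

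Peaks around cardiac genes also differed in strength between the 2 inputs of the reproducibility ranking, which the deposited list does not name as replicate 1 or 2. At 303 peaks around sarcomere genes the median log2 ratio of the second to the first input was -0.40 relative to all peaks, lower than in all 10000 random sets of equally strong peaks. It was -0.25 around cardiac transcription factors and -0.24 around calcium handling genes, again below every random set, and -0.19 around genes of metabolism and hormones (percentile 0.110). Atrial (-0.19, percentile 2.98) and ventricular genes (-0.05, 19.3) lay within the central 95% of random sets. So did endothelial (0.04, 78.5), epicardial (-0.05, 28.4), smooth muscle (-0.04, 28.7) and neural crest genes (-0.11, 12.2) and housekeeping genes (0.01, 30.7), while liver genes lay above it (0.23, 98.7). Of the remaining lists, erythroid (0.12), skeletal muscle (0.06), brain (0.13), gut, pancreas and lung (0.12), germ cell (0.02), posterior Hox (0.26), anterior Hox (0.23) and olfactory receptor genes (0.04) had positive medians within it, and immune (-0.04), epidermal (-0.12) and kidney genes (-0.04) negative ones. The random sets were drawn peak by peak, whereas a list's peaks lie in clusters around its genes. Peaks of 1 locus may move together, so the spread of random sets may be too narrow and the percentiles too extreme. With 1 library on each side there is no test between the replicates.

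**Figure D4:**
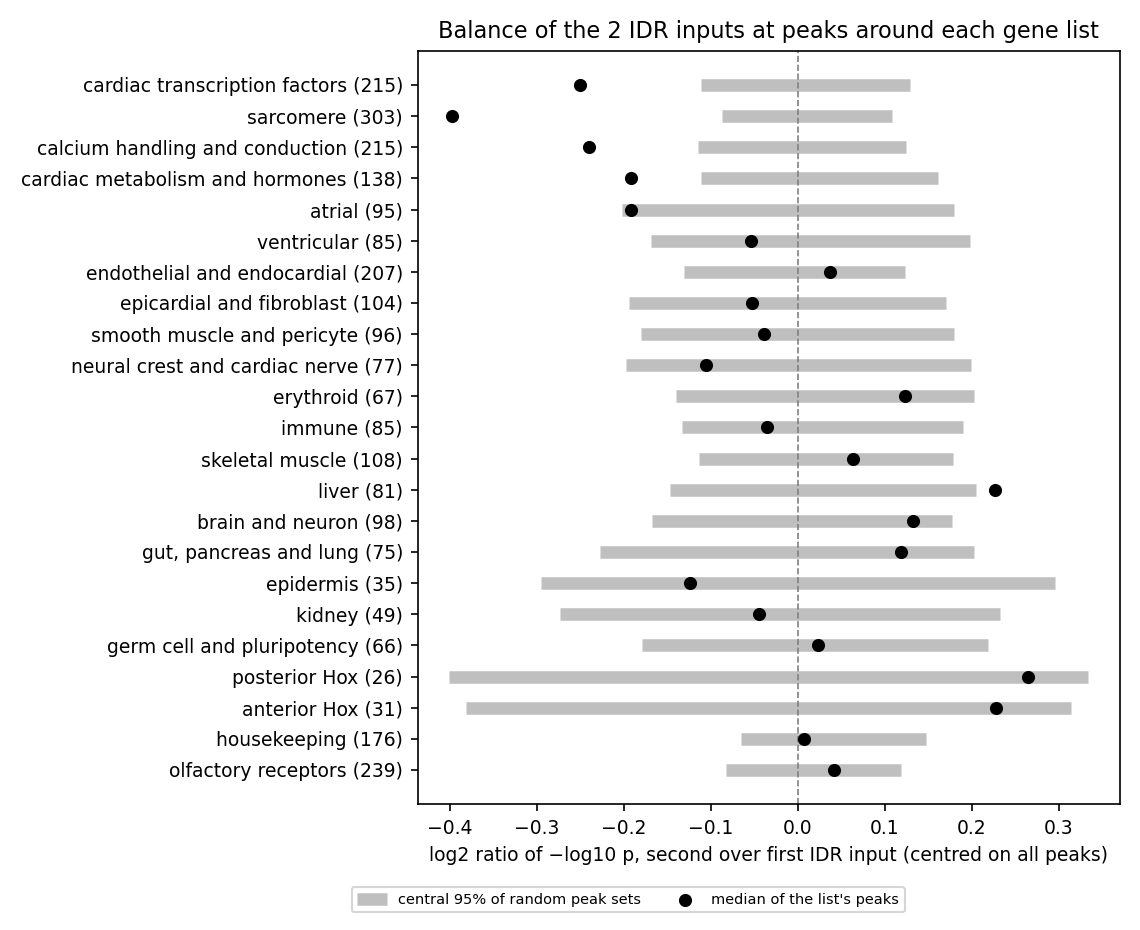
Median log2 ratio of the value (−log10 p) of the second over the first input to the reproducibility ranking at peaks around each gene list, centred on all peaks (dashed line at 0); grey bars give the central 95% of random peak sets of the same size and strength, and the number of peaks stands beside each name. Sarcomere genes lie at -0.40 and endothelial genes at 0.04.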

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

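In this part, which holds counts and no test, nothing was chosen only after the result was seen. The ranked list of the true replicates held 208 peaks on 22 sequences outside the 21 main chromosomes, which drew attention because no comparison uses them and their number is above the 3 counts that a count of 0 allows. None of its peaks (0) lay on the mitochondrial chromosome. The same list held 43331 peaks with a score of at least 540, the lowest of the conservative list, which is 235 more than the conservative list holds. This surplus drew attention because comparisons on the conservative list lack it. Ranked peaks on the main chromosomes entered the correlations and the balance of the 2 inputs. Of those past the IDR threshold, 43251 lay on the main chromosomes, as did all 20181 intervals of the conservative list. A part of the surplus therefore lay on the other sequences, and the reason for the rest was not examined.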

How the results depend on the processing

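The alternative that leaves out neighbouring list members was chosen only after the result was seen. Of 1842 values under alternatives, 1124 kept their direction and side of the threshold or stayed within the replicates' spread, 583 of those without a test moved by more, 45 were no longer past the threshold, 26 newly passed it, and 64 changed direction. Of results that passed, the 4 contrasts kept their call in 27 of 28 alternatives, the 9 distal lists in 84 of 98, the 18 promoter lists in 133 of 143, the 19 distal motifs in 97 of 113, the 23 promoter motifs in 120 of 137, and the domains in 7 of 7 (odds ratio of heart-list genes nearest to the top 100 domains, 8.75 to 21.8). Of the distal lists, smooth muscle and pericyte lost its call in 6 alternatives, atrial and housekeeping in 4 each. The cause was not tested for any change below except where the construction shows it. Unknown depth limits all statements on absent peaks.

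The share of replicate 1 intervals found in the other replicate (percent) and the share of replicate 2 intervals found in the other replicate (percent) were 59.6 and 63.8 with reciprocal overlap of 50%, 77.2 and 83.9 with IDR-thresholded lists, 76.1 and 82.4 in the strongest 50% of each list, and 75.5 and 78.8 with every summit counted. In unique intervals the rescue ratio was 1.01 and the self-consistency ratio 1.09. Pearson r and Spearman rho were 0.741 and 0.725 past the IDR threshold and 0.874 and 0.778 with 1 summit per interval. The promoter share of intervals was 26.3% and 33.2% with windows of 500 and 2500 bp, 56.2% in the conservative list, and 34.4% to 37.8% in single replicates.

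In the conservative list 5 gene lists had a higher promoter share, and the results promoter share (percent): atrial (23.1), promoter share (percent): endothelial and endocardial (50) and promoter share (percent): brain and neuron (19.4) fell below other genes. Neural crest genes turned above with pooled peaks (69.2%), 1 start site (61.5%) and 2500 bp (69.2%). Brain genes turned below in single replicates (45.2% to 48.4%), with 1 start site (54.8%), 500 bp (51.6%) and no receptor genes in the background (64.5%). Without receptor genes 0 lists had fewer distal peaks, since olfactory receptors were then left out.

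The distal ratio crossed 1 in these cases. In the conservative list 0.521 was the distal peaks ratio to random: erythroid, 0.868 the distal peaks ratio to random: immune, 0.233 the distal peaks ratio to random: kidney and 0.207 the distal peaks ratio to random: anterior Hox. With a single replicate it ranged from 0.605 to 1.11 for erythroid, 0.878 to 1.15 for immune, 0.776 to 0.917 for kidney and 0.9002 to 1.24 for anterior Hox genes. With 20 kb it was 0.298 for erythroid and 0.817 for kidney genes, 1.12 the distal peaks ratio to random: brain and neuron and 0.556 the distal peaks ratio to random: germ cell and pluripotency. With 100 kb it was 0.956 for kidney genes and 0.955 the distal peaks ratio to random: epicardial and fibroblast. Erythroid genes stood at 0.701 with pooled peaks, 0.962 with 1 start site, 0.931 without matching, 0.917 without receptor genes and 0.819 without neighbours. Kidney genes stood at 0.973 without receptor genes and without neighbours 1.04 was the distal peaks ratio to random: liver. Counting presence only gave 1.06 for liver, 1.30 for brain and 1.252 for posterior Hox genes (distal peaks ratio to random: posterior Hox). With 100 kb the contrast of mean distal peaks: endothelial and endocardial minus erythroid no longer passed (2.08). The contrast of mean distal peaks: epicardial and fibroblast minus liver, never past the threshold, changed sign (-0.197).

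Against the reversed consensus the distal ratio was 1.77 for NKX2, 0.523 for TBX, 0.361 for ETS, 1.16 for FOX, 3 for HNF1 (from few matches), 2.42 for RUNX and 0.946 for USF, and the promoter ratio 1.74 for TEAD, 1.31 for NKX2, 1.84 for MEIS, 1.90 for HAND and for FOX, 2.47 for NEUROD and 2.57 for RUNX. These ratios compare different words, so a changed direction against the reversed consensus can come from their background frequency. With the flank 1 kb away TBX stood at 0.917, SOX at 1.00 and HNF4 at 0.812 at distal and AP-1 at 0.893 at promoter summits. In the conservative list distal TBX stood at 0.792, HAND at 0.897, ERR at 0.922, YY1 at 1 and NEUROD at 0.951. Single replicates gave 0.890 to 0.8996 for TBX, 0.927 to 1.22 for ERR and 0.791 to 1.203 for HNF4.

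Motif calls that ended without a change of direction were, in the conservative list, distal NKX2 (0.703), NRF1 (5.67), FOX (0.887) and PU.1 (1.59) and promoter SRF (1.29) and MYOD (1.15). With the flank 1 kb away they were distal FOX (0.984) and promoter SRF (1.01), with 100 bp on each side promoter SRF (1.23) and HNF4 (0.673), and against the reversed consensus promoter ERR (0.810) and HNF4 (0.692). Without replicate 1 they were distal FOX (1) and RUNX (0.860) and promoter SRF (1.03) and HNF4 (0.333), and without replicate 2 distal HAND (1.06), NRF1 (2.45) and NEUROD (1.06) and promoter SRF (1.44) and ERR (0.569). Motifs that newly passed were distal ETS without replicate 1 (2.53), in the conservative list (4.43) and with the flank 1 kb away (4.08), distal ERR (1.27) and YY1 (10.3) with 100 bp on each side, and distal ERR (3.55), HNF4 (2.57) and SOX (0.663) and promoter AP-1 (1.68) against the reversed consensus. Promoter MEIS passed as lower with the flank 1 kb away (0.819).

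Gene lists that newly passed for promoters were smooth muscle and pericyte without replicate 1, with 1 start site and with 500 and 2500 bp (91.7% to 100%), neural crest below other genes in the conservative list (15.4%) and without replicate 2 (23.1%), and erythroid below them with pooled peaks (37.5%), with 500 bp (37.5%) and without replicate 2 (31.2%). For distal peaks, metabolism and hormones passed in the conservative list, in each replicate alone, with 1 start site and with 20 kb, and epicardial and anterior Hox genes when only presence was counted.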

Other observations

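The test of a lower share of cardiomyocytes, and the alternative that leaves out neighbouring list members, were chosen only after the result was seen. Some genes of other organs had many distal peaks in the replicated list although their lists as a whole did not differ from random genes in distal peaks. The replicates' own lists, given in brackets, mostly held fewer, and so did the conservative list. The intestinal regulator gene Cdx1 had 10 (5 ± 0 in the replicates, SD, n = 2) and the macrophage receptor gene Csf1r 8 (4.5 ± 0.707). They lie side by side with the mural cell receptor gene Pdgfrb, of the smooth muscle and pericyte list (9; 4.5 ± 0.707), on chromosome 18, from 61018862 to 61132149, where Cdx1 and Pdgfrb share the strongest distal peak (4.53-fold). On chromosome 2 the catecholamine enzyme gene Dbh (9; 8.5 ± 0.707) and the myoblast fusion gene Mymk (7; 6.5 ± 0.707) also share theirs (8.23-fold). Vil1 had 9 (3.5 ± 0.707), Sftpb 6 (4.5 ± 0.707), and Krt20, Sftpa1, Ins1, Ptf1a and Cdh17 had none. The skeletal troponin genes Tnnt3 (4.5 ± 2.12) and Tnni2 (5.5 ± 3.54) had 10 each. The kidney transporter gene Slc12a3 had 11 (6 ± 1.41), Pax2 5 (2 ± 0) and Six2 4 (3 ± 1.41), while Nphs2, Lrp2, Slc12a1 and Nphs1 had none. Among liver genes Apoa1 had 7 (5 ± 0), Apoc3 6 (3.5 ± 0.707) and Hnf4a 6 (1.5 ± 0.707). The neighbours Apoa1 and Apoc3 share their strongest distal peak (6.95-fold).

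In the blood lists Nfe2, an erythroid transcription factor, had 6 (3 ± 2.83) and the globin genes Hba-a2 and Hba-a1 had 5 (2.5 ± 2.12) and 4. Of these, Hba-a1 had 0 in replicate 1 and 4 in replicate 2. Gata1, Alas2, Gypa and Epb42 had none. The myeloid regulator gene Spi1 had 9 (5 ± 1.41) and Laptm5 5 (4 ± 2.83), and Cd68, Mrc1, Cd19, Itgam and Cd3e had none. In the epidermal list Perp had 8 (6.5 ± 3.54), Sfn 4 (2.5 ± 0.707) and Dsg3 2 (1.5 ± 0.707), and Krt10, Krt1, Trp63, Ivl and Flg had none. The germ cell gene Tdrd9 had 10 (6.5 ± 0.707), Zp3 5 (3.5 ± 0.707) and Nanog 4 (2.5 ± 0.707), and Dazl, Sycp1 and Zfp42 had none. In the brain list Neurod2 had 6 (4 ± 0), Slc17a7 5 (2 ± 1.41) and Snap25 3 (3 ± 0). Among Hox genes Hoxb9 (2 ± 0), Hoxb5 (2.5 ± 0.707), Hoxa3 and Hoxa4 (1.5 ± 0.707 each) had 4 each and Hoxc10 and Hoxc11 3 (2 ± 0 each), and Hoxb13, Hoxc13 and Hoxc12 had none. Olfr750 (5.5 ± 0.707), Olfr1368 and Olfr263 (3 ± 0 each) had 8 each, although their list as a whole had fewer than random genes (0.116 times). The pairs Hoxb9 and Hoxb5, Hoxa3 and Hoxa4, Hoxc10 and Hoxc11, and Olfr1368 and Olfr263 each share their strongest distal peak. Of the genes with none, Sftpa1 had 2 in replicate 1, Dazl 1 in each replicate, and Cd68, Cd19, Ptf1a, Trp63, Lrp2 and Hoxc12 1 in a single replicate's own list.

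The 10 strongest distal peaks, 28.4-fold to 55.8-fold, may largely be technical. Of these, 6 aligned to the mitochondrial genome over 50 bp or more at 80% identity or more, as copies of mitochondrial DNA in the nuclear genome would, against 2 of 1000 distal peaks drawn at random. Among all 37451 distal peaks, these 10 included, 13 aligned to it. The 30 bases at the summit occurred more than once in the genome in 5 of the 10 strongest, as for multicopy sequence, against 0 of 10 random peaks, and 8 of the 10 strongest met at least 1 of these tests. CTCF sites are argued against, since 0 of the 10 held that consensus. The peaks on chromosome X (nearest start site Pak3) and on chromosome 8 (nearest 4930467E23Rik) met neither and stay open, and no biological explanation was tested.

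The larger number of distal peaks around heart genes (107 genes, 5.77 peaks per gene) was weighed against 3 technical explanations. Gene length and isolation are argued against as the whole cause, as the ratio to genes matched for both was 2.39, a matching that the list results already used. Such matched genes had 2.41 distal peaks on average, against 2.35 over all protein-coding genes. GC content around the gene is likewise argued against as the whole cause (1.97 against genes matched on it). The random genes there were matched on GC alone, so GC acting together with length, isolation or general use was not tested. The permutation p was 2.00e-05 for both ratios, the smallest the random lists can give. General use of the gene is argued against as the whole cause, since among genes with a promoter peak the ratio was 1.99 (102 genes), but housekeeping genes also had more than random genes (1.73 times, adjusted permutation p = 0.0240), so that a part is not excluded. The pooled other-organ genes stood at 1.04 (permutation p = 0.687, 142 genes), so heart-lineage regulatory elements are a candidate explanation, as a hypothesis found and tested on the same data. A promoter peak was present in 95.3% of heart genes but 32.4% of other-organ genes, and among the latter with one the ratio was 0.885 (permutation p = 0.455, 46 genes), but with no second tissue whether these elements are specific to the heart stays open.

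Peaks around heart genes were weaker in the second input of the reproducibility ranking (median log2 ratio -0.28 over 929 peaks). Wider scatter of strong or weak peaks, a difference between promoter and distal peaks and GC content of the peaks are each argued against as the whole cause, as the median stayed at percentile 0 of 2000 random sets matched on 20 classes of strength, on promoter or distal position, and on GC. The medians of these random sets were 0.00396, 0.000856 and 0.00409. These sets too were drawn peak by peak, so the percentiles may be too extreme. A lower share of cardiomyocytes in one library may explain it, but peaks of the heart's other cell types lay at percentile 39.15 (median -0.02, 484 peaks), neither raised nor lowered, so this stays open. Peaks of other-organ genes lay at percentile 97.05 (median 0.09). The 2 pools of embryos can differ in stage or dissection, which was not tested, and the inputs are not named as replicates.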
